A study of Homo sapiens with 12 samples.

How the data were processed

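HEK293T is an established human embryonic kidney cell line. Per the labels' protocols, the cells received 20 µM STM2457, an inhibitor of the m6A methyltransferase METTL3, in 0.2% (v/v) DMSO, or 0.2% DMSO alone, for 6 h. An extra 10% of fetal bovine serum was added 1 h before lysis, and cycloheximide, which halts elongating ribosomes, was present at 100 µg/ml for the last 3 min. Poly(A)-selected, strand-specific RNA-seq libraries were made from 4 replicates per arm and ribosome profiling (Ribo-seq) libraries of 26 to 34 nt footprints from 2 replicates per arm. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

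The deposited RNA-seq files hold raw read counts per gene, and the same files hold counts of 92 ERCC spike-in sequences. Per the submitters' processing notes, FastQC 0.11.9, STAR 2.7.3a, UMI-tools 1.1.2, bedtools 2.29.2, Subread 2.0.3 with featureCounts, SAMtools 1.10 and DESeq2 were used with GRCh38.p12, with no role or order given. The count files list 60662 Ensembl genes, of which 60261 matched a symbol. The series table covers 12224 genes, 12216 of them with a symbol, and holds a normalized signal per library. For the Ribo-seq libraries the low values are whole multiples of a step per library, as reads divided by a factor by the authors would give. The RNA-seq columns were not examined in this way. The table's columns of mean signal are the authors' means, and for RNA they equal the mean of replicates 1 to 3 in all 12224 genes. The authors' translational efficiency in the table is the ratio of the mean footprint signal to the mean RNA signal per arm, and the authors' change of efficiency is given on a log2 scale without a p-value.

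RNA changes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM normalization, filterByExpr, Benjamini-Hochberg adjusted p under 0.05), with spike-in sequences left out. Standard errors of edgeR fold changes are the absolute log2 fold change divided by the square root of the F statistic. CPM values were computed with TMM factors, and log2 CPM used a prior count of 2. Gene lists fixed before the data were examined were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, where at least 5 members passed the filter. Camera compares the members of a list with the other filtered genes. This gave 29 tested lists of 30. The alternatives included DESeq2 1.42.0.

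Footprint signals of the table were whole multiples of the worth of 1 read per library, with 100% of the values within 0.1 of a whole read, so footprint reads could be recovered. Footprint and efficiency changes were tested with limma on log2(signal + 1), so these fold changes are on that scale. For genes with few footprint reads they can be larger or smaller in size than with the edgeR interaction described below. C7orf31 efficiency changed by -2.50 with limma and -2.01 with edgeR, and ZNF33B efficiency by -1.79 and -2.06. Genes with a mean of at least 10 recovered reads per footprint library were kept, which left 10906. The filter and the pseudocount were set after the files were opened.

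Efficiency was tested as the interaction of assay and treatment in 3 fits. The fit planned before the data were examined uses a shared spread for RNA-seq and Ribo-seq libraries and is given as the main result. A fit with a weight per assay and an edgeR interaction on the deposited RNA counts and recovered footprint reads were added after the calls of the planned fit and its test on simulated data had been seen. On simulated data for 10906 genes with none changed, the planned fit made 128 calls and the weighted fit 0. With 200 changed genes, 62.6% of the 396 calls of the planned fit were false, against 10.4% of the 106 calls of the weighted fit. At a 2-fold change of efficiency, they recovered 90% and 70% of the changed genes. The weighted fit was therefore read beside the planned one for each named gene.

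On simulated RNA-seq counts of 17602 genes, edgeR recovered 49.0%, 69.4%, 88.0% and 95.9% of genes changed by 1.25, 1.5, 2 and 3 fold. Of its 166 calls 10.2% were false. Only 200 genes were changed in this simulation, against 8511 RNA calls in the data, so these shares need not hold for those calls. For footprints, limma recovered 12% of 1.25-fold, 52% of 1.5-fold, 80% of 2-fold and 92% of 3-fold changes among 10906 genes, with 4.84% of 124 calls false.

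Named genes were chosen by a rule set before the data were examined. For RNA these were the 12 largest increases and 12 largest decreases among genes with adjusted p under 0.05, a mean of at least 5 CPM, a symbol that is not a clone name, and no overlap between the arms in log2 CPM. For footprints and efficiency the rule took 10 in each direction. METTL3, METTL14, WTAP, FTO, ALKBH5 and YTHDF2 were named in any case, and the examples of each list come from its 4 members with the smallest p. FTH1, FTL, TFRC, SLC40A1, SLC11A2 and EPAS1 were named after the ferritin values had been seen, and a further gene of this group is not reported here.

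Genes were assigned by symbol to the X chromosome or autosomes, and to gene classes such as protein-coding and lncRNA, from a RefSeq table of GRCh38.p14. Genes with no class there, such as SLC16A4-AS1, were counted neither as protein-coding nor as lncRNA. Per-library scores were compared by exact two-sided permutation tests, whose smallest possible p is 0.0286 for 4 against 4 libraries. Alternatives changed the normalization, the test, the filters, the replicate block, the threshold and the libraries used. Sets of replicates 1 and 2 and of replicates 3 and 4 were also fitted alone, because a principal component with 10.8% of the variance separated them in both arms. Sequence motifs of m6A were not analysed here. Antisense genes were counted from strand-specific libraries, but the strand setting of the counting is not given in the sources used here. Table RNA values are not the deposited gene counts: WTAP RNA changed by 1.11 in the table and by 0.80 in the counts. Reads shared with pseudogenes or paralogs, as of SMG1P7, ribosomal protein and ferritin genes, leave their values uncertain.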

Results

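The data comprise 8 RNA-seq libraries and 4 Ribo-seq libraries of HEK293T cells treated with the METTL3 inhibitor STM2457 or with DMSO. RNA-seq files held 43291730 to 51645739 counts per library. The recovered footprint reads of the series table numbered 4711513 and 3198063 in the DMSO libraries and 4039314 and 3898620 in the STM2457 libraries. The comparison asks how RNA levels, ribosome footprints and translational efficiency differ when m6A is depleted, as the series design states.

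RBM15 (ENSG00000162775.16, chromosome 1), a subunit of the m6A writer complex, rose from 48.1 ± 2.33 to 212 ± 16.3 CPM (SD, n = 4 per arm), a 4.41-fold increase. YTHDF2 (ENSG00000198492.16, chromosome 1), an m6A reader that recruits mRNA decay factors, rose 3.04-fold from 164 ± 4.74 to 498 ± 8.19 CPM. HNRNPLL (ENSG00000143889.16, chromosome 2), a splicing regulator, fell by 2.04 on the log2 scale (SE 0.05), and SDHAF1, an assembly factor of succinate dehydrogenase, fell from 20.6 ± 0.981 to 4.97 ± 0.345 CPM. METTL3 (ENSG00000165819.12, chromosome 14) was at 75.7 ± 6.71 CPM with DMSO and 83.3 ± 6.71 CPM with STM2457, which did not pass the test (log2 fold change 0.14, SE 0.07, edgeR quasi-likelihood adjusted p = 0.104). The METTL3 RNA log2 fold change did pass with a replicate block (edgeR adjusted p = 0.000534) and turned to -0.06 with ERCC spike-in scaling.

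The other largest increases were those of GNB3 (log2 fold change 2.05), SMG1P7 (2.01), ZNF503 (1.84), ERRFI1 (1.82), DEPP1 (1.70), BAMBI (1.69), CHAC1 (1.64), ZNF703 (1.64), HOXD13 (1.63) and ID3 (1.61). ERRFI1 is a feedback inhibitor of the EGF receptor, BAMBI a pseudoreceptor of TGF-β signalling and ID3 an inhibitor of helix-loop-helix transcription factors. The other largest decreases were ATP6V0E2-AS1 (-2.30), SLC16A4-AS1 (-2.13), SMIM10 (-1.95), ATXN7L3B (-1.88), PCLO (-1.82), TFIP11-DT (-1.81), DHFR2 (-1.77), CIRBP-AS1 (-1.66), CHML (-1.64) and TRIM69 (-1.58). SMG1P7 is a pseudogene and can share reads with SMG1. In these 24 genes the 4 STM2457 libraries did not overlap the 4 DMSO libraries, as in 7955 of 17807 genes where chance gives 2.86%, and edgeR adjusted p ranged from 9.54e-13 for ZNF503 to 1.2e-05 for GNB3.

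**Figure D1:**
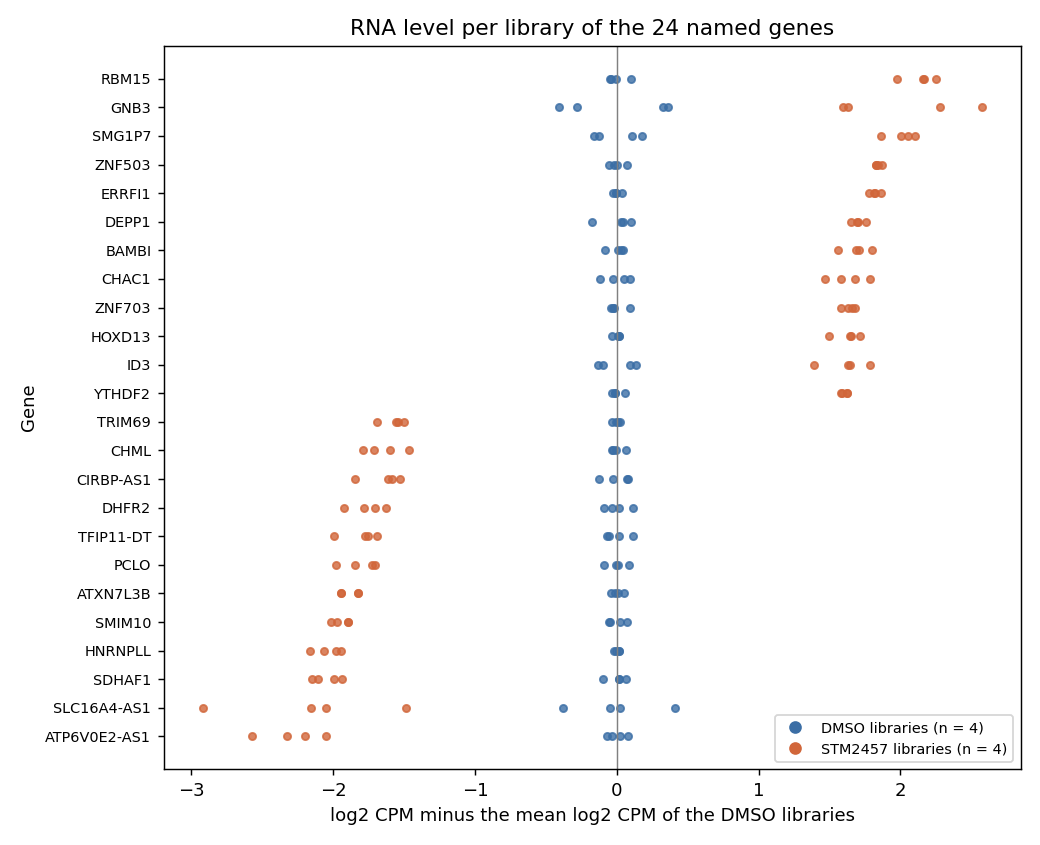
RNA level of the 24 genes named by the rule, as log2 CPM minus the mean of the DMSO libraries (x axis), with 1 point per library. The 4 STM2457 libraries lie on 1 side of the 4 DMSO libraries for each gene, from RBM15 (log2 fold change 2.14) to ATP6V0E2-AS1 (-2.30).

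Among 17807 genes tested, 4669 were higher and 3842 lower with STM2457 at an edgeR adjusted p under 0.05, of which 1225 and 987 changed by at least 1.5 fold. Replicates 1 and 2 alone gave 4333 higher and 3602 lower genes, and replicates 3 and 4 alone 3721 and 2770. Of 8504 called genes tested in both sets, 8503 had the same sign in each. The genes were called on all 8 libraries, which include both sets, so much of this agreement follows from the selection. The changes above are relative to the TMM scaling. With the ERCC spike-ins as the scaling, an alternative chosen after seeing the data, the median gene moved by -0.19 on the log2 scale, and 2159 genes were higher and 8383 lower. Without STM2457 replicate 4, which had the highest ERCC share, the median gene moved by -0.16, with 2464 higher and 7517 lower.

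Of the 8 tested members of the m6A writer complex 7 rose and none fell, with a median log2 fold change of 0.62. Beside RBM15, its paralog RBM15B rose by 1.14, WTAP by 0.80, CBLL1 by 0.69 and METTL14 by 0.55. The camera adjusted p of the list was 0.000121, and the adjusted p was 0.231 with an estimated correlation. With ERCC scaling 5 members were higher and 0 lower (median 0.42). Among m6A readers, YTHDF1 (0.79), YTHDF3 (0.84) and YTHDC1 (0.52) rose with YTHDF2, while the list of 13 (6 higher, 2 lower) did not pass camera (adjusted p = 0.0639). With ERCC scaling 4 readers were higher and 6 lower, with a median of -0.13, and without STM2457 replicate 3 the list passed (camera adjusted p = 0.0189). The demethylase ALKBH5 rose by 0.43, and FTO had a log2 fold change of -0.09 (edgeR adjusted p = 0.0714). The FTO RNA log2 fold change passed with a replicate block (edgeR adjusted p = 0.0233) and with ERCC scaling (-0.29), among other alternatives. METTL16 rose by 0.71 and METTL5 fell by 0.42 in the list of other m6A methyltransferases (3 higher, 1 lower of 5, camera adjusted p = 0.723).

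Of 20 tested transcripts described elsewhere as m6A-methylated, 14 rose and 1 fell (median 0.52, camera adjusted p = 0.000609, adjusted p = 0.269 with an estimated correlation). Some lists share members, so their results are not independent. MYC, JUN, JUNB and KLF4 are also in the immediate early list, CREBBP and EP300 in the histone enzyme list and ZNF703 in the zinc finger list. ATF4, ASNS and ATF3 are in both the nonsense-mediated decay target list and the ATF4 target list, and ATF3 is also in the immediate early list. These overlaps are examples, and other lists share members as well. MYC rose by 1.27 and the acetyltransferase gene CREBBP by 0.85, whereas TAF7 fell by 0.77, and with ERCC scaling 11 were higher and 4 lower (median 0.33). Immediate early and serum response genes rose in 26 of 33 cases (median 0.52, camera adjusted p = 1.55e-06, adjusted p = 0.231 with an estimated correlation), among them DUSP1 (0.91), NR4A2 (1.02) and IER5 (0.60). With ERCC scaling 21 of them were higher and 2 lower (median 0.33). Histone lysine methyltransferases and acetyltransferases rose in 19 cases and fell in 2 of 25 (median 0.33, camera adjusted p = 3.28e-05, adjusted p = 0.231 with an estimated correlation). SETD2 rose by 0.94, KAT6A by 0.99 and EP300 by 0.69, and with ERCC scaling 13 of the list were higher and 6 lower (median 0.13). Zinc finger genes of the ZNF series rose in 222 and fell in 54 of 421 cases (median 0.20, camera adjusted p = 8.4e-06, adjusted p = 0.231 with an estimated correlation), but with ERCC scaling 121 were higher and 120 lower.

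Cytosolic ribosomal protein genes rose in 76 of 79 cases by a small amount (median 0.18, camera adjusted p = 4.63e-15, adjusted p = 0.269 with an estimated correlation), for example RPS9 (0.25) and RPL3 (0.24). With ERCC scaling their median turned to -0.01, with 0 higher and 3 lower. ATF4 targets of the integrated stress response rose in 17 and fell in 1 of 23 cases (median 0.25, camera adjusted p = 0.000773, adjusted p = 0.231 with an estimated correlation), including SLC7A5 (0.49) and DDIT4 (1.34), and with ERCC scaling 8 were higher and 5 lower. Nonsense-mediated decay targets rose in 13 and fell in 1 of 16 cases (median 0.29, camera adjusted p = 0.00919, adjusted p = 0.531 with an estimated correlation), with ATF4 at 0.29 and ZFAS1 at 0.36, and with ERCC scaling 3 were higher and 3 lower. WNT pathway genes rose in 13 and fell in 3 of 28 cases (median 0.13, camera adjusted p = 0.00574, adjusted p = 0.231 with an estimated correlation). In this list ZNRF3 rose by 1.11, AXIN1 by 0.80 and FZD1 by 1.00, and with ERCC scaling 9 were higher and 9 lower (median -0.06).

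Mitochondrially encoded mRNAs rose in 11 of 13 cases (median 0.22, camera adjusted p = 0.0273, adjusted p = 0.789 with an estimated correlation), with MT-CO3 at 0.15 and MT-CO2 at 0.20. With ERCC scaling 0 of the 13 passed, MT-CO3 turned to -0.04, and the list's call was lost, as it was without DMSO replicate 3, DMSO replicate 4 or STM2457 replicate 2. G2/M cell cycle genes fell in 16 and rose in 2 of 31 cases (median -0.09, camera adjusted p = 0.00416, adjusted p = 0.782 with an estimated correlation). UBE2C fell by 0.38 and CDC20 by 0.43, both cofactors of the anaphase-promoting complex, while CCNF rose by 0.31, and with ERCC scaling 26 fell and 0 rose (median -0.29). Adjusted over the list alone, higher and lower members numbered 27 and 1 of the immediate early, 227 and 57 of the zinc finger, 14 and 3 of the WNT, and 14 and 1 of the nonsense-mediated decay target genes. The other 7 of the 11 lists past camera had equal counts adjusted over the list alone.

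The remaining lists did not pass camera with TMM scaling. Higher and lower members numbered 17 and 30 of 75 mitochondrial ribosomal proteins, 23 and 13 of 74 nuclear-encoded oxidative phosphorylation subunits, and 14 and 9 of 42 translation factors. They numbered 16 and 6 of 29 deadenylation and decapping genes, 4 and 1 of 15 nonsense-mediated decay factors, and 8 and 7 of 20 codon-dependent decay and ribosome quality control genes. SMG8 (1.34), PELO (1.02), USP10 (0.76) and BTG2 rose in these lists, and UQCR11 fell by 0.82. Counts were 11 and 4 of 22 p53 targets, 7 and 3 of 16 unfolded protein response genes, 3 and 1 of 22 interferon-stimulated genes, and 7 and 10 of 23 cholesterol synthesis genes. They were 13 and 6 of 32 G1/S genes, 9 and 5 of 24 homologous recombination genes, and 2 and 4 of 7 S-adenosylmethionine genes. Markers of other cells gave 0 and 0 of 7 for fibroblasts, 2 and 0 of 6 for epithelial carcinoma lines, and 0 and 1 of 5 for blood cells. The 2 m6A demethylases were too few for a list test. Adjusted over the list alone, the counts became 18 and 31 for mitochondrial ribosomal proteins, 15 and 9 for translation factors and 8 and 3 for the unfolded protein response. They became 13 and 7 for G1/S genes, 1 and 0 for epithelial markers and 1 and 1 for the demethylases, and were otherwise equal.

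With ERCC scaling most of these counts moved down. Higher and lower members became 0 and 46 of the oxidative phosphorylation subunits, 1 and 26 of the translation factors and 7 and 53 of the mitochondrial ribosomal proteins. They became 4 and 13 of the deadenylation genes, 1 and 11 of the nonsense-mediated decay factors, 3 and 10 of the codon-dependent decay genes and 7 and 8 of the p53 targets. G1/S genes became 4 and 19, unfolded protein response genes 2 and 8, homologous recombination genes 5 and 15, interferon-stimulated genes 2 and 8 and cholesterol synthesis genes 4 and 13. S-adenosylmethionine genes became 0 and 5, other m6A methyltransferases 1 and 3, and fibroblast, epithelial and blood markers 0 and 3, 0 and 1, and 0 and 2. With this scaling 12 lists passed camera, 9 higher and 3 lower than the other genes. Higher is relative here: cytosolic ribosomal protein genes passed as higher with 0 members higher and 3 lower than with DMSO. Of the 12 lists, 2 were lower and had not passed before. These were mitochondrial ribosomal proteins (camera adjusted p = 0.0374) and oxidative phosphorylation subunits (camera adjusted p = 0.0264).

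**Figure D2:**
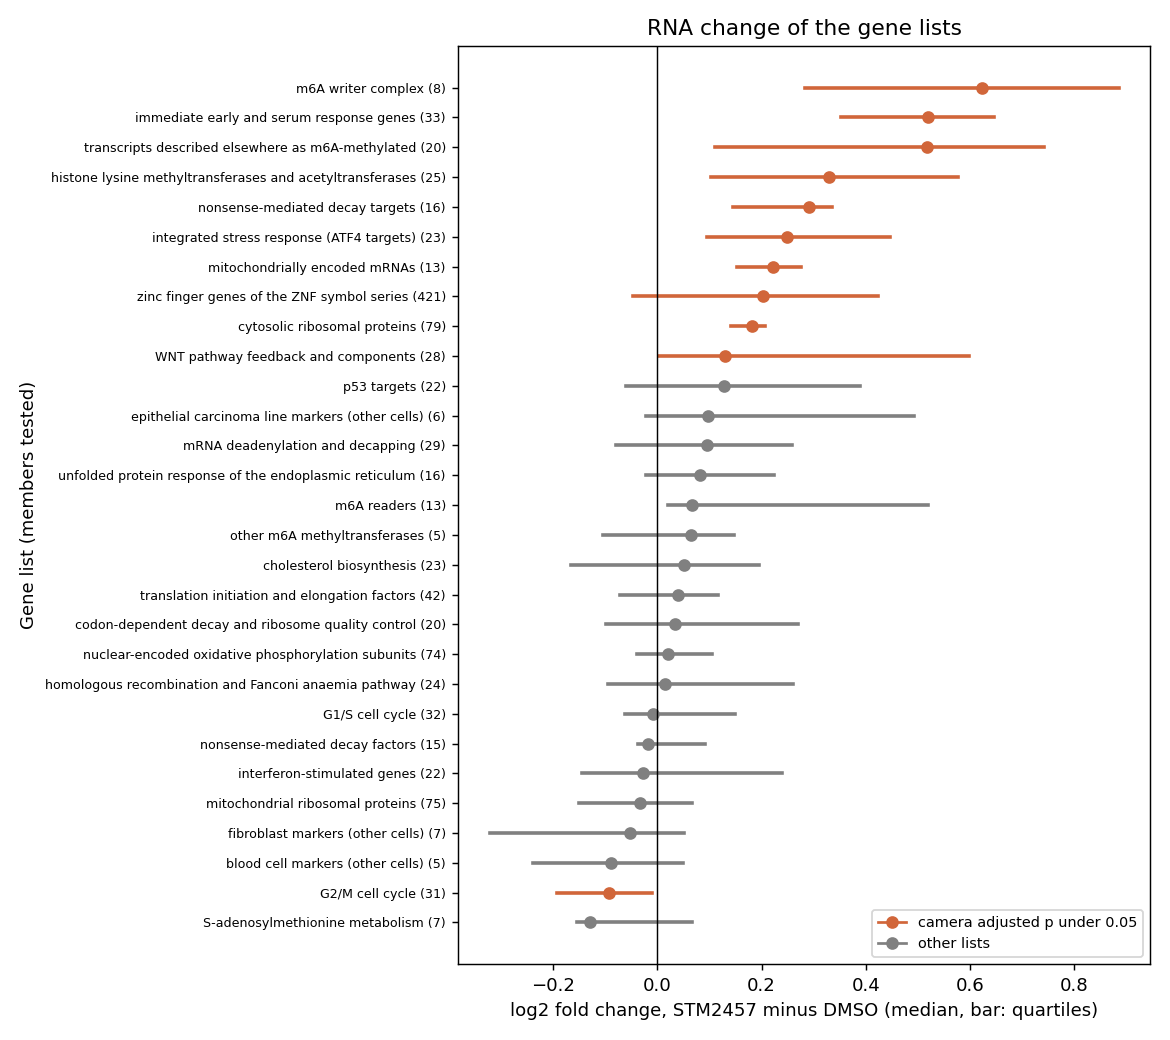
Median log2 fold change of RNA (points) and quartiles (bars) of the 29 tested gene lists, STM2457 minus DMSO. The m6A writer complex had the highest median (0.62), and the orange lists passed camera at the preset correlation.

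The next comparison asks whether m6A depletion raised autosomal transcripts more than X-linked ones, over protein-coding genes. Of 467 X-linked genes 108 rose and 112 fell, against 4117 and 2704 of 13041 autosomal genes. The score of X-linked minus autosomal mean log2 CPM was 0.0786 ± 0.0116 with DMSO and 0.0162 ± 0.0154 with STM2457 (SD, n = 4), a difference of -0.06 (exact two-sided permutation p = 0.0286, the smallest 4 against 4 libraries can give). The difference was -0.06 within replicates 1 and 2 and within replicates 3 and 4, where 2 against 2 libraries cannot give a p under 0.333. With a median in place of a mean it was -0.10, and the same score of each autosome differed by -0.03 to 0.05. As a gene list, X-linked genes did not pass limma's camera. That test set them against all other filtered genes, lncRNA genes included, and so not against autosomal protein-coding genes alone.

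RBM15 footprints rose from a normalized signal of 1970 ± 31.9 to 9576 ± 544 (SD, n = 2 per arm), a log2 change of 2.28, and YTHDF2 by 1.69. WTAP rose by 1.76 and METTL14 by 0.61, while METTL3 was at 0.03 (limma adjusted p = 0.911). ALKBH5 footprints, at 0.23 (limma adjusted p = 0.163), and FTO footprints, at 0.08 (limma adjusted p = 0.769), did not pass. HNRNPLL fell from 1097 ± 22.6 to 143 ± 35.5, a log2 change of -2.96, and WDR6 from 4848 ± 375 to 873 ± 146 (-2.48).

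CHAC1, an enzyme that breaks down glutathione, rose in footprints from a normalized signal of 66.7 ± 5.77 to 439 ± 35.8 (SD, n = 2). Further increases, on the log2 scale, were SPSB2 (2.24), PARS2 (1.99), TMEM74 (1.94), FICD (1.91), HOXD10 (1.89), FEM1C (1.84), ZNF449 (1.83) and ID3 (1.83). Further decreases were ZDBF2 (-3.05), ATXN7L3B (-3.03), ZBTB26 (-2.90), ZNF33B (-2.84), PCNX4 (-2.82), SDHAF1 (-2.81), TSPYL4 (-2.66) and CHML (-2.45). Among 10906 genes, limma called 1046 higher and 669 lower, and edgeR on recovered reads called 1112 and 607, of which 1638 genes were shared. Without DMSO replicate 1 limma called 797 higher and 367 lower. Without DMSO replicate 2 it called 742 and 262, 1004 in all, and FICD, SPSB2 and ZBTB26 no longer passed, and HOXD10 did not pass without DMSO replicate 1. Without DMSO replicate 1 and without replicate 2, the SPSB2 footprint log2 fold change was 3.31 and 1.16, the FICD footprint log2 fold change 2.60 and 1.22, and the HOXD10 footprint log2 fold change 1.29 and 2.48. The CHML footprint log2 fold change was -3.11 without STM2457 replicate 1 and -1.79 without replicate 2.

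Across 10906 genes the RNA and footprint changes correlated with Pearson r = 0.705 and Spearman rho = 0.642, with a slope of 0.929, genes not being independent replicates. Of genes tested in both, 1007 rose and 467 fell in RNA and footprints, where independent lists would share 371 and 149, and 51 genes were called in opposite directions. RNA and efficiency changes correlated weakly (r = -0.08), and with the RNA change and the RNA part of efficiency taken from separate sets of RNA-seq libraries r was -0.07 and -0.02.

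**Figure D3:**
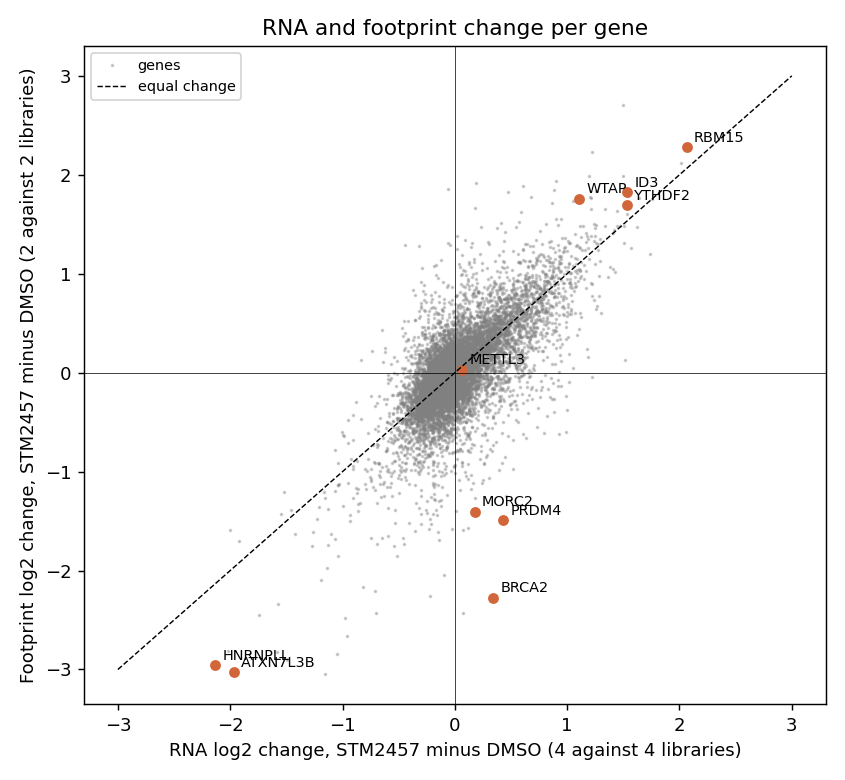
Log2 change of footprints (y axis) against that of RNA (x axis) per gene, STM2457 minus DMSO, both from the series table, with named genes in orange. RBM15 and YTHDF2 lie near the line of equal change, and BRCA2 (footprint change -2.27) lies far below it.

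Translational efficiency, footprint signal relative to RNA signal, fell most among the named genes for BRCA2 (ENSG00000139618.15), a homologous recombination factor. Its footprint signal went from 748 ± 5.92 to 165 ± 83.9 (SD, n = 2), a log2 efficiency change of -2.62. PRDM4 (-1.92) and MORC2 (-1.58) also fell, and HOXB2 (1.48) and RECK (1.26), an inhibitor of metalloproteinases, rose. With RNA-seq replicates 1 and 2 only, the calls of HOXB2, RECK and the other 8 named increases were lost, while BRCA2, PRDM4 and MORC2 passed. Footprint libraries carry only the replicate numbers 1 and 2, so this setting compares same-numbered libraries of both assays. The planned fit also uses the RNA-seq libraries of the other replicates, which a principal component separated from replicates 1 and 2. This setting also has fewer RNA-seq libraries, so the lost calls cannot tell these reasons apart. WTAP efficiency rose by 0.65 in both limma fits, with adjusted p of 0.000217 in the planned fit and 0.00418 with a weight per assay. With the edgeR interaction, which uses the deposited RNA counts, it rose by 0.97 (edgeR adjusted p = 2.97e-06). The WTAP efficiency log2 fold change was 0.52 with weights and without the footprint library of DMSO replicate 1 (limma adjusted p = 0.0809). METTL3, METTL14, FTO, ALKBH5 and YTHDF2 did not pass the test of efficiency in any of the 3 fits with all libraries. Without the footprint library of STM2457 replicate 2 the FTO efficiency log2 fold change was 0.32 (limma adjusted p = 0.0257) and the YTHDF2 efficiency log2 fold change 0.24 (limma adjusted p = 0.00683) in the planned fit, and neither passed with weights.

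The planned limma fit called 339 genes higher and 486 lower, the fit with a weight per assay 25 and 88, and the edgeR interaction 94 and 428. Restricted to RNA-seq replicates 1 and 2, which carry the same numbers as the footprint libraries, the planned fit called 7 higher and 50 lower. The weighted and edgeR fits were chosen after seeing the data. On simulated data with no change the planned fit made 128 calls, so its count is not a reliable number of changed genes. In all 3 fits 20 genes rose and 83 fell. Of the 20 genes named by the rule, CELSR3 (1.73), FICD (1.72), HOXB2, NMRK1 (1.38), CYP2R1 (1.26), RECK, BRCA2, C7orf31 (-2.50), PRDM4, ZNF33B (-1.79), CRYBG3 (-1.72), TSPYL4 (-1.70), ANKRD12 (-1.58) and MORC2 also passed the weighted fit. JAK2, FRMD5, ZNF449, HOXD10, ZDBF2 and TUBGCP6 did not pass the weighted fit, and CELSR3, FRMD5, HOXD10, ZDBF2 and TUBGCP6 did not pass edgeR. The footprint changes of CELSR3, NMRK1, JAK2, RECK and ANKRD12 did not pass (limma adjusted p = 0.0504, 0.0537, 0.0603, 0.0633 and 0.238). The normalized RNA signal of ANKRD12 rose by 0.99 on the log2 scale, beside a footprint change of -0.60. All 10 named increases had few footprints, with a mean of 15.5 (NMRK1) to 40 (ZNF449) reads per library. None of them was kept when a mean of at least 50 reads was required. The named decreases ranged from 11.5 (C7orf31) to 205 (MORC2). The C7orf31 efficiency log2 fold change did not pass without either DMSO footprint library in the planned fit (limma adjusted p = 0.0560 and 0.0763), and was -3.92 without STM2457 replicate 1 and -1.08 without replicate 2. Without DMSO replicate 1 and without replicate 2, the CELSR3 efficiency log2 fold change was 2.42 and 1.04, the FICD efficiency log2 fold change 2.41 and 1.03, and the HOXD10 efficiency log2 fold change 0.68 and 1.87. Without STM2457 replicate 2 HOXD10 did not pass (limma adjusted p = 0.0559). In the authors' deposited table the log2 change of efficiency of BRCA2 was -2.49 and that of WTAP 0.65.

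**Figure D4:**
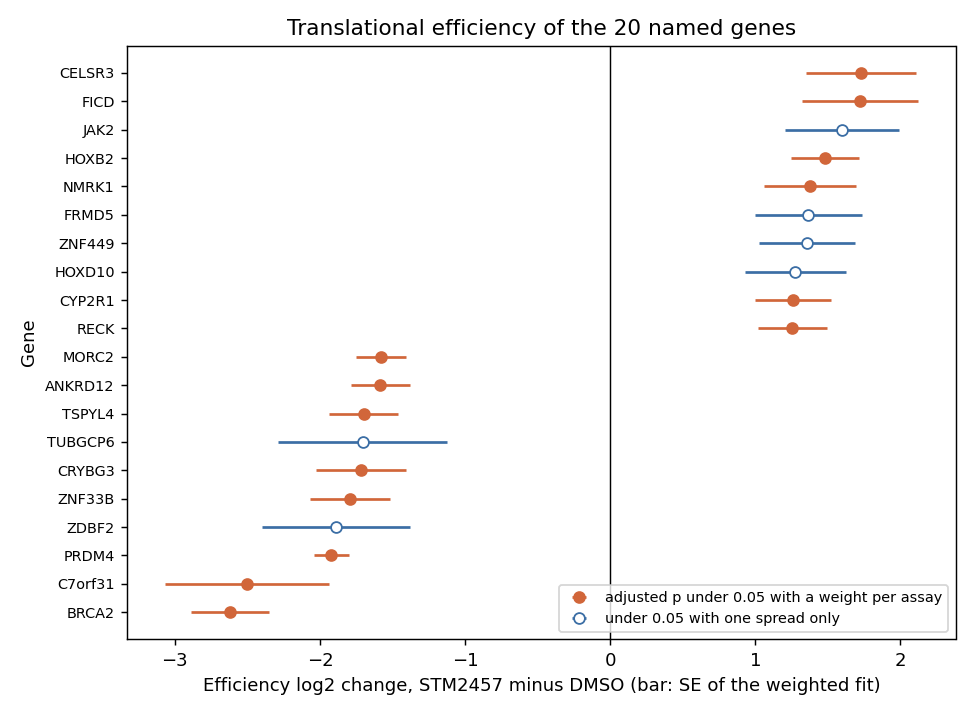
Log2 change of translational efficiency (x axis) of the 20 genes named by the rule, with the SE of the fit with a weight per assay. Filled points are the 14 genes with adjusted p under 0.05 in that fit, among them BRCA2 (-2.62).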

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

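The tests of the ERCC share by permutation and with each library left out, and of other splits of the libraries, were chosen after the results were seen. ERCC spike-ins, which are not genes and were left out of the gene tests, took 0.403% ± 0.00949 of the counts with DMSO and 0.433% ± 0.0224 with STM2457 (SD, n = 4), with all 4 STM2457 libraries above all 4 DMSO libraries. STM2457 replicate 4 was highest (0.466%), and without it the STM2457 mean was 0.422% and the log2 ratio of the shares fell from 0.105 to 0.0683. The exact two-sided permutation p of 0.0286, the smallest possible or 0.0571 with any 1 of the DMSO libraries left out, restates the difference that prompted it, so an amount that varied by library stays open. Fewer counts in a few abundant genes would lower the log2 ratio of ERCC to gene counts once these are left out, but it was 0.112 without the 100 most abundant and the mitochondrial genes, against 0.104 with all genes. A lower RNA content of treated cells and a difference in the spike-in amount given to each arm also stay open, as the sources used here do not say how the spike-ins were added.

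In 5 of 138 groups of 4 libraries a library lay far from the other 3, where chance gives about 1 in 20. These were ZNF703 (415 CPM, the nearest library at 383), CBLL1 (44.7 and 46.8 CPM), TAF7 (102 and 97.6 CPM), ZFAS1 (24.3 and 26.0 CPM) and the ERCC share (0.389% and 0.407%), all in the DMSO arm, the ERCC share in replicate 1.

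The real split of the 8 RNA-seq libraries gave 8511 changed genes, and 1 of the 35 splits, the real one, gave as many. The highest other count was 121, in the split of replicates 1 and 2 against 3 and 4. A share of 1 in 35 is the smallest that these splits can give. No other split came near the real count, but this alone does not exclude chance. For gene lists chance was not excluded, since 7 of the 35 splits, the real one included, gave as many as 11 lists, the highest other count being 12. The other splits with as many lists all kept 3 libraries of an arm together and so hold part of the treatment difference, which limits what this count can show. Those with 2 and 2 reached 4 lists.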

How the results depend on the processing

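RNA counts stayed within 1.5 times the main 8511 genes except with the fold of at least 1.5 (2212), and leaving out each library gave 7790 to 8647. The 11 changed lists became 0 with an estimated correlation, where 6 lists had an unadjusted p under 0.05, and 23 with fry, and leaving out a library gave 10 to 12. The efficiency count of 825 became 113 with a weight per assay, 522 with edgeR, 57 with RNA-seq replicates 1 and 2 only, 321 with replicates 1 to 3 only, 1372 at adjusted p under 0.1 and 297 under 0.01. Leaving out a footprint library raised it to 1242 to 1906 in the planned fit and lowered it to 37 to 100 with weights (49 without DMSO replicate 1, 45 without STM2457 replicate 2), the lone library being assumed to vary like the others. With a footprint library left out, the footprint count of 1715 became 1004, without DMSO replicate 2, to 1464, and other settings gave 1621 to 1719. The correlation of RNA and footprint changes was 0.737 for genes with a mean of at least 10 CPM, 0.770 for genes with an RNA change and 0.792 for at least 50 reads, and that of RNA and efficiency changes was -0.019 with RNA changes from RNA-seq replicates 1 and 2 and the RNA part of efficiency from replicates 3 and 4. The X score difference was -0.0669 to -0.0555 without a library, -0.104 with a median in place of a mean, and -0.0604 and -0.0644 in the 2 sets of replicates, too few for a test. The METTL3 RNA log2 fold change turned to -0.0568 and the MT-CO3 RNA log2 fold change to -0.0417 with ERCC scaling. The METTL3 efficiency log2 fold change ranged from -0.158 to 0.0856, the latter without STM2457 replicate 2, and the METTL3 footprint log2 fold change was -0.0924 without STM2457 replicate 1. The causes were not tested. For the X-linked list against all other filtered genes, camera gave p = 0.494, and p = 0.738 with an estimated correlation. METTL3 RNA passed with no filter, without DMSO replicate 4 or STM2457 replicate 2, and in each set of 2 replicates (adjusted p 0.0147 and 0.0449).

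With a replicate block the counts were 9542 for RNA, 11 for lists, 632 for efficiency and 1719 for footprints, and the block ended the call of C7orf31 efficiency. Same-numbered RNA-seq libraries deviated together with correlations of 0.151, 0.227, 0.148 and 0.0763 over all filtered genes. Over genes with a mean of at least 1 CPM they were 0.392, 0.495, 0.341 and 0.143. All were positive, and only that of replicate 4 over all filtered genes missed a threshold of 0.1. The main fits left the block out, as the labels do not say that the numbers are pairs. The correlations do not show that the libraries are unpaired, so the block results stand beside the main ones. Replicate 4 correlated best with replicate 3 of the other arm. Over 1088 alternative values of 64 named RNA genes, 1067 kept direction and side of the threshold. Apart from those named in any case, these genes were chosen for a large change or a small p. Their count therefore does not speak for RNA calls in general. Among 28 efficiency values of named genes, those of METTL3, METTL14, FTO, ALKBH5 and YTHDF2 had not passed the planned fit. Of the others, 12 were no longer past the threshold with RNA-seq replicates 1 and 2 only, and 6 with weights. The motif classes were not run, as no genome was used here.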

Other observations

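The camera tests on efficiency were chosen after the results were seen, and the ferritin and lncRNA patterns were found in these data before their tests were set. SNHG small nucleolar RNA host genes rose in 19 and fell in 2 of 23 cases (median log2 fold change 0.32, or 0.12 with ERCC scaling). Among them SNHG1, SNHG12 and SNHG15 are also in the nonsense-mediated decay target list. Efficiency of cytosolic ribosomal protein genes was below 0 in 62 of 70 cases with a median log2 change of -0.19, while 26 fell and 3 rose past the planned limma test and 5 and 1 past the weighted one. Efficiency falls where RNA rises and footprints do not, and their footprints had a median change of -0.07, with 2 higher and 9 lower of 70 (camera adjusted p = 0.128). Camera on the efficiency changes, chosen after seeing the data, gave an adjusted p of 3.32e-10, and an adjusted p of 0.651 with an estimated correlation. Histone lysine methyltransferases and acetyltransferases had a median efficiency change of -0.15, with 6 lower and 1 higher of 25 in the planned fit and 2 and 0 with weights (camera adjusted p = 0.018, adjusted p = 0.908 with an estimated correlation).

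FTH1 and FTL, the subunits of the iron store ferritin, rose in footprint signal from 410 ± 60.9 to 969 ± 16.2 and from 444 ± 13.1 to 1122 ± 13.5 (SD, n = 2), and their efficiency rose with limma adjusted p of 0.00211 and 0.000253 in the fit with a weight per assay. The RNA log2 fold change was 0.09 for FTH1, which did not pass the test, and 0.15 for FTL. If reads shared with pseudogenes shifted all such genes alike, other genes with many pseudogenes would rise as well. Over 100 other genes with at least 10 pseudogenes the upper quartile of the efficiency change was 0.0579. It was 0.114 over the 63 of them whose symbols do not start with RPL or RPS. Sharing can differ by gene, so an effect particular to the ferritin pseudogenes stays open. The tables argue against a single library, since the lowest change of either gene with a footprint library left out was 1.08, although FTH1 then missed the threshold with weights (limma adjusted p = 0.0535). Iron-responsive control may account for the ferritin rise, as TFRC RNA, which is destabilised when iron is high, changed by -0.37. However, 3842 genes fell, and SLC11A2 RNA rose by 0.20. Efficiency moved upward for SLC40A1 (1.22, SE 0.59, limma adjusted p = 0.236) and EPAS1 (0.36, limma adjusted p = 0.118) but did not pass the test. SLC40A1 footprint signal was low (29.0 ± 27.3 with DMSO and 44.5 ± 19.9 with STM2457, SD, n = 2), so its missed test cannot decide.

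Of 1364 lncRNA genes 130 rose and 452 fell (median -0.18), against 4225 and 2816 of 13508 protein-coding genes (median 0.02), with medians of -0.37 and -0.18 with ERCC scaling. Low expression was tested with protein-coding genes matched on mean CPM, and 0 of 1000 draws had a median as low, the lowest being -0.05. Reads from sense genes were tested over 531 pairs of an antisense gene and its sense gene, whose changes correlated with a Spearman rho of -0.0219 across genes. A biological explanation was not tested.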
